A study of Homo sapiens with 10 samples.

How the data were processed

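RNA from HT29 and t-hESC cells was sequenced after 48 hours of treatment, as 10 libraries in 5 groups of 2. Libraries were made from total RNA with a TruSeq RNA v2 kit, which does not mark strand, per the labels' protocols. The treatment field of the labels reads 48 hours of DMSO for every sample, so groups, compounds and replicate numbers were taken from the sample titles. The titles give no time, and the 48 hours stands in that field. The submitters' processing notes name fastp 0.20.1, FastQC 0.11.9, STAR, DESeq2 1.34.0 and the builds GRCh38 and hg38, with no roles. The counting program and the annotation release are not given in the sources used here, so how reads shared by near-identical or overlapping genes were counted is unknown.

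The deposited table holds raw counts, which are whole numbers with different totals per library, for 60651 genes and 1181 repeat families. The authors also deposited 4 tables of comparisons, with a log2 fold change and its standard error in each. The authors' adjusted p-values stand beside them and are missing where they did not adjust. In the authors' tables for t-hESC many log2 fold changes lie closer to 0 than those computed here, and whether they were shrunken is not given in the sources used here, so the authors' tables are used only for counts of calls and their direction. The count table has 4 further columns that match no sample, and they were not used here. Gene symbols and coordinates came from a reference table of the GRCh38.p14 assembly, and 38352 gene identifiers had a symbol.

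Total gene counts per library ran from 13137026 to 24492838. A count of 0 allows a level of up to 3 counts, or 0.122 to 0.228 CPM, and this covers counting error only. Repeat families were left out of library sizes. Counts were fitted with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr with a minimum count of 10 (22495 genes kept), and the quasi-likelihood F test with robust estimation over all 10 libraries, which leaves 5 residual degrees of freedom beside 56.7 prior ones. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called. CPM were computed here from the counts and the library sizes scaled by those normalization factors. The comparisons were BIX and VXN against DMSO in t-hESC, VXN against DMSO in HT29, VXN against BIX, the difference of the VXN effects between the lines, and the lines under DMSO and under VXN.

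The text draws on 45 gene lists with 981 genes, all found in the count table and 3 of them by an older symbol, fixed together with the tests and the alternatives before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the lists with at least 5 measured members, and again with a correlation estimated per list. Named genes follow a rule set at the same time. It takes, per comparison, the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 4 CPM and with all libraries of one group above those of the other, up to 4 members of each list with the smallest p, and EHMT1, EHMT2, POU5F1, NANOG and SOX2. Genes named for one comparison are also given in others, and some genes that meet the rule are not reported here.

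The tests were checked on simulated counts for 21473 genes with known changes. For BIX in t-hESC 62, 90, 94 and 98% of genes changed by 1.2, 1.5, 2 and 4-fold were recovered, and 6.01% of calls were false. For VXN in HT29 the shares were 50, 92, 90 and 94%, with 3.55% false. For the difference between the lines they were 14, 82, 88 and 94%, with 1.22% false. A list shifted by 0.3 on the log2 scale was recovered. Its genes were drawn independently and all shifted alike, so the check does not cover lists of correlated genes. The simulation changed 200 genes for BIX and for VXN in HT29, and 225 for the difference between the lines. Its counts were drawn with edgeR's own estimates of the spread. The data gave far more calls, so the shares of false calls need not hold there.

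The alternatives were size factors of the DESeq2 type, upper-quartile factors, DESeq2 1.42.0, no count filter, a minimum count of 50, only the groups compared, the replicate number as a block, a fold threshold, an estimated correlation for lists, and each library left out in turn. Upper-quartile factors for the lists, the repeat families, the gene length trend and a count without rises that t-hESC carry-over would cover were added after seeing the data. Groups of 2 libraries allow neither a test for outlying samples nor other splits of the samples.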

Results

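RNA was sequenced from 10 libraries of cultured human cells, 2 in each of 5 groups. HT29 is an established colorectal cancer cell line. The line t-hESC is given in the labels as transformed pluripotent stem cells. Cells of both lines received the solvent DMSO or 10 µM of VXN for 48 hours, and t-hESC cells also received 1 µM of BIX. VXN is a code name that the labels do not expand. BIX is a name in use for an inhibitor of the histone H3 lysine 9 methyltransferases G9a and GLP, which the genes EHMT2 and EHMT1 encode, and the series title puts the work under pharmacological change of dimethylation at that residue. Gene counts came to 24475240 and 23423001 in the HT29 DMSO libraries, 24492838 and 21138502 in HT29 VXN, 18095537 and 21128261 in t-hESC DMSO, 15302336 and 13137026 in t-hESC BIX, and 16295315 and 17232437 in t-hESC VXN. At these depths a count of 0 allows a level of up to 0.122 to 0.228 CPM (counts scaled to the size of the library) in a library, for counting error only. Correlations of log expression between libraries ran from 0.991 to 0.996 within groups and from 0.645 to 0.681 between the lines. The series describes the 2 libraries of a condition as biological replicates. Their spread was small, with a common biological coefficient of variation of 0.021, and chi-square values per degree of freedom between replicates ran from 1.19 to 1.85 over genes. The p-values measure only the spread between these libraries.

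The first comparison asked which transcripts BIX changed in t-hESC. Genes of the extracellular matrix and a histone methyltransferase gene were among those that rose. KMT2D, a histone H3 lysine 4 methyltransferase gene (chromosome 12, 49018978 to 49060794, GRCh38), went from 28.7 ± 0.36 to 69.1 ± 0.83 CPM (SD, n = 2), a log2 fold change of 1.27 ± 0.062 (SE). HSPG2, which encodes the basement membrane proteoglycan perlecan, rose from 50.4 ± 0.64 to 116 ± 6.9 CPM (SD, n = 2), and FN1, the fibronectin gene, from 64 ± 1.8 to 136 ± 5.4 CPM (SD, n = 2). By the rule for named genes (a mean of at least 4 CPM) the highest log2 fold change was that of PLA2G2A, a secreted phospholipase gene (chromosome 1, 19975431 to 19980434), with a log2 fold change of 2.10 ± 0.13 (SE). Log2 fold changes were 1.42 ± 0.19 for the serotonin receptor gene HTR2C, 1.39 ± 0.18 for the peptide receptor gene GRPR, 1.21 ± 0.19 for the Nodal antagonist gene LEFTY1 and 1.17 ± 0.14 for CD2, and HMCN1 went from 8.84 ± 0.69 to 21.1 ± 0.09 CPM (SD, n = 2). CYP26A1, which encodes an enzyme that degrades retinoic acid, fell by 1.43 ± 0.12 on the log2 scale, from 18.5 ± 0.0074 to 6.84 ± 0.13 CPM (SD, n = 2). DHRS2 and CORO1A fell by 0.95 and 0.93. Among these genes the largest edgeR adjusted p was 2.91e-06, for DHRS2.

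Genes of growth and DNA replication fell together under BIX. Of 32 cytosolic ribosomal protein genes all 32 fell, also when adjusted over the list alone, with a median log2 fold change of -0.19 (camera adjusted p = 3.58e-30, and adjusted p = 0.0395 with an estimated correlation). Examples are RPS27A at -0.29 ± 0.028 and RPS18 at -0.28 ± 0.028 (SE), and many such genes have near-identical pseudogenes that could share reads. Of 28 genes of ribosome biogenesis and MYC targets 24 fell, 2 rose and 2 were not called (26 fell and 2 rose when adjusted over the list alone), with a median of -0.32 (camera adjusted p = 1.04e-21). ODC1, the first enzyme of polyamine synthesis, fell from 249 ± 0.2 to 158 ± 3.4 CPM (SD, n = 2), and NPM1 and NOP56 fell by 0.35 and 0.42 on the log2 scale. NPM1 and HSP90AA1 also have close pseudogene copies that could share reads. Of 32 genes of the G1/S transition and DNA replication 25 fell, 2 rose and 5 were not called (27 and 2 when adjusted over the list alone), at a median of -0.27 (camera adjusted p = 3.92e-16). MCM6 and MCM7, of the replicative helicase, fell by 0.40 ± 0.037 and 0.29 ± 0.031 (SE), and PCNA, the sliding clamp gene, by 0.34. Among 32 genes of the G2/M list 14 fell and 3 rose (17 and 3 when adjusted over the list alone; camera adjusted p = 0.00392). With an estimated correlation the adjusted p was 0.293, and with a stricter count filter it was 0.0732. The proliferation marker gene MKI67 rose by 0.67 ± 0.038 and CENPF by 0.41, while CCNB1 fell by 0.29. Heat shock genes fell in 10 of 17 cases and rose in 1 (10 and 2 when adjusted over the list alone; camera adjusted p = 5.79e-07), among them HSP90AA1 at -0.44 ± 0.028. Of 25 nuclear genes of oxidative phosphorylation 19 fell and 6 were not called (21 fell when adjusted over the list alone; camera adjusted p = 2.37e-13, and adjusted p = 0.0635 with an estimated correlation), for example ATP5F1B at -0.26. Over 11521 genes the log2 fold change under BIX rose with the length of the gene on the genome (Spearman's rho 0.301 across genes, which are not independent replicates). Under VXN in the same cells rho was -0.0174. Single genes that rose under BIX, KMT2D, HSPG2, FN1 and MKI67 among them, were not examined with that trend removed.

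Other groups moved upward or apart. Of the 13 mRNAs encoded in the mitochondrial genome 12 rose and 1 was not called (all 13 rose when adjusted over the list alone), with a median of 0.42 (camera adjusted p = 2.35e-31). MT-ND4 went from 1400 ± 3.4 to 2340 ± 46 CPM (SD, n = 2), and MT-ND5 rose by 0.77 ± 0.03 (SE). Of 17 fibroblast and stromal genes 8 rose, 1 fell and 8 were not called (8 rose and 2 fell when adjusted over the list alone; camera adjusted p = 3.38e-05, and adjusted p = 0.0635 with an estimated correlation), with the collagen genes COL5A2 at 0.70 ± 0.059 and COL1A2 at 0.76 ± 0.064. Of 26 targets of p53, 11 rose and 2 fell (12 and 2 when adjusted over the list alone; camera adjusted p = 0.000124), including the cell cycle inhibitor gene CDKN1A at 0.37 ± 0.05 and the death receptor gene TNFRSF10B at 0.38. Cholesterol genes rose in 10 of 25 cases and fell in 2 (11 and 2 when adjusted over the list alone; camera adjusted p = 0.00221, and adjusted p = 0.0635 with an estimated correlation), with SC5D at 0.55 and SREBF2 at 0.29. Metallothionein and zinc genes fell in 6 of 9 cases, also when adjusted over the list alone, at a median of -0.99 (camera adjusted p = 7.28e-05). MT1E, MT1F, MT1X and MT2A fell by 2.61, 1.09, 0.99 and 0.87. These copies share sequence, so the split of reads among them is uncertain.

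The genes of the enzymes themselves were not called under BIX. EHMT1 (chromosome 9, 137619005 to 137836127) was at 140 ± 3.6 and 144 ± 4.4 CPM (SD, n = 2), with a log2 fold change of -0.037 ± 0.040 (SE) and an edgeR adjusted p of 0.579. EHMT2 (chromosome 6, 31879759 to 31897698) was at 210 ± 12 and 205 ± 2.2 CPM (SD, n = 2), with a log2 fold change of 0.035 ± 0.037 (SE). Of 27 genes of the H3K9 methylation machinery 9 rose, 6 fell and 12 were not called (12 rose and 6 fell when adjusted over the list alone; camera adjusted p = 0.0395, and adjusted p = 0.145 with an estimated correlation). That call was also lost with a stricter count filter (adjusted p = 0.056) and without HT29 VXN replicate 1 (0.0528) or 2 (0.0519), t-hESC BIX replicate 1 (0.0763) or 2 (0.0512), or t-hESC DMSO replicate 2 (0.0751). CBX5 (heterochromatin protein 1 alpha) rose by 0.30 and the demethylase gene KDM4B by 0.34, and UHRF1 fell by 0.38. The pluripotency genes went both ways. POU5F1 was at 1690 ± 64 CPM against 1690 ± 21 (SD, n = 2; edgeR adjusted p = 0.977). SOX2, NANOG and DPPA4 rose by 0.15, 0.22 and 0.13, and LIN28A fell by 0.24. Without t-hESC DMSO replicate 2 the calls of SOX2, NANOG and DPPA4 were lost, with edgeR adjusted p of 0.0956, 0.0751 and 0.0522. POU5F1 and NANOG have near-identical pseudogenes, so their counts carry that uncertainty.

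In all, edgeR called 5199 of 22495 genes under BIX, 2456 higher and 2743 lower, with 195 and 37 of them at 2-fold or more. The balance of directions turned with the scaling, to 2669 higher and 2457 lower with size factors of the DESeq2 type. DESeq2 called 3158, 1606 higher and 1552 lower. The authors' deposited table called 678 genes, 370 higher and 308 lower, of which 677 were called here in the same direction. The reverse did not hold. Among the genes named above as higher or lower it called, for example, KMT2D, FN1 and ODC1. It did not call DHRS2, MT-ND4, MT-ND5, COL1A2, COL5A2, MCM6, MCM7, PCNA, NPM1, RPS18, RPS27A, ATP5F1B or SREBF2. Nor did it call MKI67, CENPF, CCNB1, CDKN1A, LIN28A, SOX2, NANOG or DPPA4. HTR2C, GRPR, LEFTY1, CD2 and MT1F had no adjusted p in it.

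The second comparison asked what VXN changed in the same cells. Immediate early genes, the first to answer growth factor and stress signals, rose together, and so did the genes of cholesterol synthesis. EGR1 (chromosome 5, 138465479 to 138469303) went from 1.06 ± 0.57 to 12 ± 0.081 CPM (SD, n = 2), a log2 fold change of 3.46 ± 0.18 (SE), and FOS and JUN rose by 2.30 ± 0.17 and 1.94 ± 0.065. HMGCS1, which makes the substrate of the rate-limiting step of cholesterol synthesis (chromosome 5, 43287470 to 43313412), went from 473 ± 7.4 to 1290 ± 22 CPM (SD, n = 2). NPTX1, a neuronal pentraxin gene (chromosome 17, 80466834 to 80476607), fell by 3.45 ± 0.16 on the log2 scale, from 15.3 ± 0.31 to 1.39 ± 0.025 CPM (SD, n = 2).

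Of 26 genes of the immediate early and AP-1 list 25 rose and 1 fell, also when adjusted over the list alone, with a median of 0.80 (camera adjusted p = 4.84e-32). SPRY4 and DUSP6, feedback inhibitors of the ERK pathway, rose by 1.24 ± 0.036 and 0.96 ± 0.030, and IER2 by 1.11. Of 25 cholesterol genes 24 rose and 1 fell, also when adjusted over the list alone, with a median of 0.88 (camera adjusted p = 8.48e-53). INSIG1, DHCR7 and FDFT1 rose by 1.44, 1.14 and 0.88, and ABCA1, the cholesterol exporter gene, fell by 1.33 ± 0.12. Fatty acid genes rose in 11 of 17 cases and fell in 3, also when adjusted over the list alone (camera adjusted p = 1.35e-08), with ACSS2 at 1.94 ± 0.042 and the desaturase gene SCD at 0.66. All 13 mitochondrial mRNAs rose, also when adjusted over the list alone, at a median of 1.19 (camera adjusted p = 1.32e-52). MT-ND4 was at 3890 ± 85 CPM against 1400 ± 3.4 (SD, n = 2), and MT-ATP6 and MT-ND1 rose by 1.39 and 1.23. MT-ATP6 has a near-identical nuclear copy that could share its reads. The mRNAs took 3.09% ± 0.014 of gene counts under VXN and 1.45% ± 0.0044 under DMSO (SD, n = 2), while the mitochondrial rRNAs took 0.295% ± 0.029 and 0.269% ± 0.0075. Of 26 targets of p53, 20 rose and 1 fell (21 and 1 when adjusted over the list alone; camera adjusted p = 2.78e-11), including CDKN1A at 0.99 ± 0.046 and TNFRSF10B at 0.67. Targets of TGF-beta and Nodal rose in 10 of 19 cases, also when adjusted over the list alone (camera adjusted p = 3.65e-05), with SMAD7 at 0.80. ATF4 target genes rose in 16 of 33 cases and fell in 4, also when adjusted over the list alone (camera adjusted p = 1e-04, and adjusted p = 0.0943 with an estimated correlation). GDF15, a stress cytokine gene, rose by 2.15 ± 0.072, the receptor gene TLR4 by 2.39 ± 0.18 and the adhesion gene ICAM1 by 1.81.

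Lower groups under VXN in t-hESC included replication, glycolysis and growth. Of 32 genes of G1/S and DNA replication 28 fell and 4 were not called (28 when adjusted over the list alone; camera adjusted p = 7.2e-27), and MCM2, MCM4 and MCM6 fell by 0.66, 0.63 and 0.66. Of 32 G2/M genes 17 fell and 1 rose (18 and 1 when adjusted over the list alone; camera adjusted p = 6.59e-07, and adjusted p = 0.0924 with an estimated correlation), with BUB1 at -0.36 and PLK1 at -0.33. Of 19 glycolytic genes 16 fell and 2 rose (17 and 2 when adjusted over the list alone; camera adjusted p = 5.09e-16, and adjusted p = 0.0576 with an estimated correlation). PGAM1, ENO1 and PKM, which have close pseudogene copies, fell by 0.46, 0.39 and 0.35. Ribosome biogenesis and MYC target genes fell in 22 of 28 cases (22 fell and 1 rose when adjusted over the list alone; camera adjusted p = 2.58e-13), ODC1 among them at -0.62. Metallothionein and zinc genes fell in 6 of 9 cases, also when adjusted over the list alone (camera adjusted p = 9.29e-06), with MT1F, MT1X and MT2A at -1.53, -1.36 and -0.86. Heat shock genes fell in 8 of 17 cases and rose in 3 (9 and 3 when adjusted over the list alone; camera adjusted p = 0.00168, and adjusted p = 0.0924 with an estimated correlation). Cytosolic ribosomal protein genes fell in 26 of 32 cases (27 when adjusted over the list alone, camera adjusted p = 1.89e-11, and adjusted p = 0.0924 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell in 15 of 25 cases, also when adjusted over the list alone (camera adjusted p = 2.02e-08, and adjusted p = 0.0943 with an estimated correlation). STC1 fell by 2.00 ± 0.12, LPCAT1 by 1.11 and RNF145 by 1.14.

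EHMT1 fell by 0.29 ± 0.040 and EHMT2 by 0.23 ± 0.038 (SE) under VXN in t-hESC, from 144 ± 4.4 to 118 ± 1.6 and from 205 ± 2.2 to 175 ± 4.6 CPM (SD, n = 2). Of the 27 genes of the H3K9 methylation machinery 10 fell and 3 rose (10 and 6 when adjusted over the list alone; camera adjusted p = 0.016, and adjusted p = 0.0924 with an estimated correlation), including UHRF1 at -0.68 and the demethylase gene KDM1A at -0.31. Among 28 pluripotency genes 10 fell and 5 rose (11 and 7 when adjusted over the list alone; camera adjusted p = 0.0223). The adjusted p was 0.337 with an estimated correlation, 0.059 with no count filter and 0.067 with the replicate number as a block, and it was 0.056 without t-hESC DMSO replicate 1, 0.0568 without t-hESC VXN replicate 1 and 0.0502 without HT29 VXN replicate 2. The Nodal co-receptor gene TDGF1 fell by 0.66, DNMT3B by 0.45, SOX2 by 0.32 and POU5F1 by 0.13, and NANOG rose by 0.41. SOX9 rose by 1.31 ± 0.072, from 14.8 ± 0.36 to 36.8 ± 0.32 CPM (SD, n = 2). In all, edgeR called 6531 genes, 3254 higher and 3277 lower, with 345 and 119 at 2-fold or more, and DESeq2 called 4086. The balance of directions depended on the scaling, with 2913 higher and 3749 lower under upper-quartile factors and 3289 and 3233 under size factors of the DESeq2 type. The authors' deposited table called 1210 genes, 615 higher and 595 lower, of which 1209 were tested and 1208 called here in the same direction. Among genes named above it did not call PGAM1, ENO1, PKM, SCD, BUB1, EHMT2 or POU5F1, and MT1F had no adjusted p in it.

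The third comparison set the compounds against each other in t-hESC, at doses that differ (10 µM of VXN and 1 µM of BIX), so compound and dose cannot be separated. The immediate early and cholesterol genes were higher under VXN. FOS was at 9.37 ± 1.9 CPM under VXN and 1.61 ± 0.22 under BIX (SD, n = 2), and EGR1 and JUN differed by 2.74 ± 0.17 and 2.20 ± 0.073 on the log2 scale (SE). HMGCS1 was higher by 1.31 ± 0.030, INSIG1 by 1.26 and ACSS2 by 1.58. NPTX1 was at 1.39 ± 0.025 CPM under VXN and 29.7 ± 1.1 under BIX (SD, n = 2), a difference of -4.41 ± 0.15 (SE).

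Of 26 immediate early and AP-1 genes 24 were higher under VXN and 2 were not called (25 higher when adjusted over the list alone; camera adjusted p = 2.2e-38), among them DUSP6 at 1.17 and SPRY4 at 1.16. Of 25 cholesterol genes 22 were higher and 1 lower (22 and 2 when adjusted over the list alone; camera adjusted p = 2.79e-55). All 13 mitochondrial mRNAs were higher under VXN, also when adjusted over the list alone, at a median of 0.65 (camera adjusted p = 2.18e-48). Of 19 glycolytic genes 16 were lower and 3 not called (16 lower and 1 higher when adjusted over the list alone; camera adjusted p = 5.37e-18), with PKM at -0.58 and PGK1 at -0.59. Of the 27 genes of the H3K9 methylation machinery 15 were lower and 12 not called, also when adjusted over the list alone (camera adjusted p = 4.98e-08), including EHMT2 at -0.26 ± 0.039, EHMT1 at -0.25 ± 0.041, KDM3B at -0.33 and KDM4B at -0.43. Stromal genes were lower in 7 of 17 cases and higher in 1 (9 and 1 when adjusted over the list alone; camera adjusted p = 3.61e-05, and adjusted p = 0.0595 with an estimated correlation), with COL5A2 at -1.09 and COL1A2 at -0.83. Pluripotency genes were lower in 12 of 28 cases and higher in 5 (15 and 6 when adjusted over the list alone; camera adjusted p = 0.000781, and adjusted p = 0.218 with an estimated correlation). TDGF1 was lower by 0.62, SOX2 by 0.47 and POU5F1 by 0.13. NANOG was higher by 0.19 with edgeR (adjusted p = 0.00713) but not with DESeq2 (adjusted p = 0.128), nor with edgeR without t-hESC BIX replicate 1 (adjusted p = 0.0932). For the metallothionein gene MT1X the difference was -0.38, with a 95% interval from -0.67 to -0.085 and an edgeR adjusted p of 0.0528. It passed the threshold with size factors of the DESeq2 type (adjusted p = 0.0443), upper-quartile factors (0.0379), a stricter filter (0.045) and without t-hESC BIX replicate 2 (0.00238), where the difference was -0.62. Without t-hESC BIX replicate 1 it was -0.041 (adjusted p = 0.941). For MT1F the difference was -0.43, with an interval from -0.87 to 0.0047 (edgeR adjusted p = 0.159), and without t-hESC VXN replicate 1 it was -0.81 (adjusted p = 0.0284) and without replicate 2 -0.12 (adjusted p = 0.822). Across 11521 genes, which are not independent replicates, the difference between VXN and BIX fell with gene length on the genome (Spearman's rho -0.342). The lists of this comparison were not examined with that trend removed. In all, 5110 genes differed with edgeR, 2600 higher and 2510 lower under VXN, and 2982 differed with DESeq2. The balance of directions turned with the scaling, to 2193 higher and 2909 lower with upper-quartile factors, 2389 and 2696 with size factors of the DESeq2 type and 1310 and 1672 with DESeq2, and without t-hESC BIX replicate 2 it was 1889 and 1988.

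The calls of both compounds in t-hESC were set side by side. Of the 2456 genes higher under BIX and the 3254 higher under VXN, 1184 were shared, where independent lists would share 355. Of the 2743 and 3277 lower genes 1581 were shared, where independent lists would share 400, and 239 genes were called in opposite directions. Both comparisons use the same DMSO libraries, so the lists are not independent. Across 13789 genes, which are not independent replicates, the log2 fold changes correlated at r = 0.436 with a covariance of 0.0314, and 69.9% of genes had the same sign. In 20 simulations of unchanged groups against shared controls the mean r was 0.453, the mean covariance 0.00401 and the mean share of genes with the same sign 65.6%, and edgeR's shared calls numbered at most 0. The simulated groups hold no changed genes, so they do not give the sharing that common controls would add between lists of changed genes.

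**Figure D1:**
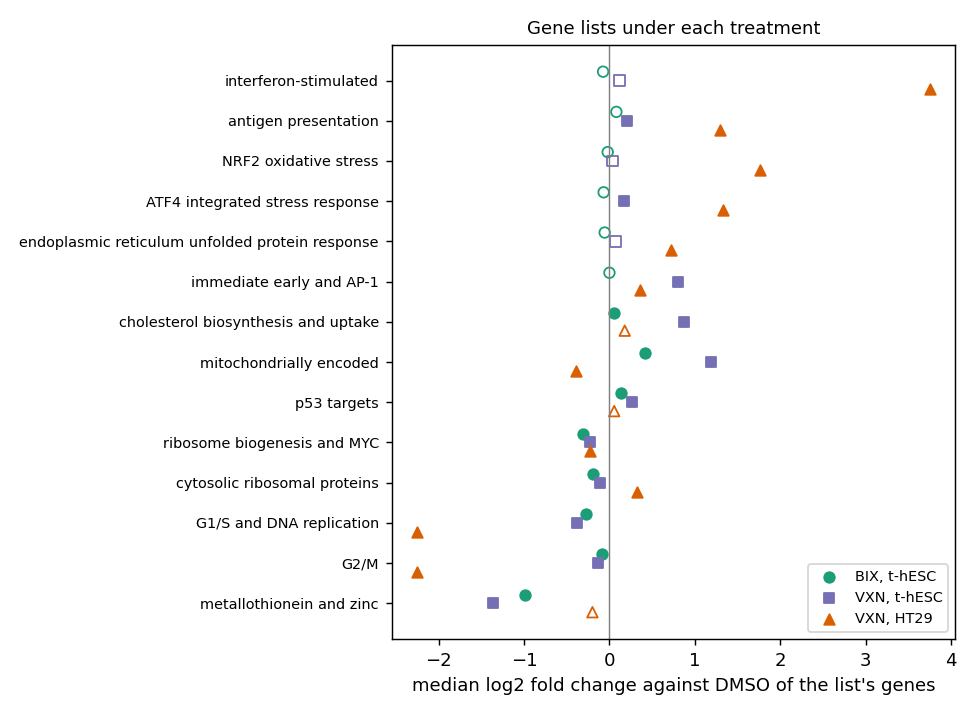
Median log2 fold change against DMSO (horizontal axis) of the genes of 14 lists for BIX in t-hESC (circles), VXN in t-hESC (squares) and VXN in HT29 (triangles), with filled symbols where camera's adjusted p was under 0.05 and open symbols elsewhere. The interferon-stimulated list stands at 3.75 under VXN in HT29 and at 0.12 in t-hESC, and the mitochondrially encoded list at -0.39 in HT29 and 1.19 in t-hESC.

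The next comparison asked what VXN changed in HT29. Interferon-stimulated genes, which mediate defence against viruses, had the highest list median, and cell cycle genes fell. IFI6 (chromosome 1, 27666064 to 27672192) went from 1.65 ± 0.17 to 213 ± 0.62 CPM (SD, n = 2). TOP2A, which encodes the topoisomerase of dividing cells, went from 641 ± 6.3 to 104 ± 2.2 CPM (SD, n = 2). LGR5, a marker of intestinal stem cells (chromosome 12, 71439129 to 71586310), fell from 24.8 ± 0.5 to 0.767 ± 0.15 CPM (SD, n = 2).

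All 37 interferon-stimulated genes measured rose 2-fold or more, also when adjusted over the list alone, with a median log2 fold change of 3.75 (camera adjusted p = 4.17e-33). OAS2, a sensor of double-stranded RNA, rose by 6.93 ± 0.12 and NLRC5 by 7.01 ± 0.20. RSAD2, XAF1 and IFI44L had 1, 3 and 3 counts over the DMSO libraries and 14.7 ± 1.7, 26.2 ± 0.31 and 22.7 ± 1.5 CPM under VXN (SD, n = 2). Of 16 antigen presentation genes 15 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 2.48e-09), with TAP1 at 2.83 and HLA-C at 1.57, an HLA gene whose reads can be shared with its relatives. Of 22 NF-kappaB and inflammatory genes 19 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 4.11e-06), among them LCN2 at 3.24 ± 0.036, IL32 at 4.40 and ICAM1 at 2.60. LAMP3 rose by 8.00 ± 0.13.

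Genes of the NRF2, ATF4 and unfolded protein response lists rose as well, while heat shock genes fell. Of 25 genes of the NRF2 oxidative stress list 23 rose and 1 fell (23 and 2 when adjusted over the list alone; camera adjusted p = 8.45e-18). The aldo-keto reductase genes AKR1C1 and AKR1C2 rose by 6.07 and 6.89, with reads that could be split between these near-identical copies. The ferritin genes FTH1 and FTL, which also have close copies, rose by 2.47 and 2.50. Of 33 ATF4 target genes 29 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 3.87e-17), with DDIT3 at 3.56 ± 0.053, DDIT4 at 2.62 and TRIB3 at 2.49. Of 22 genes of the endoplasmic reticulum unfolded protein response 20 rose and 2 were not called, also when adjusted over the list alone (camera adjusted p = 3.44e-13). The chaperone gene HSPA5 went from 465 ± 5.9 to 2120 ± 10 CPM (SD, n = 2), and HERPUD1 and HYOU1 rose by 1.97 and 1.82. Of 17 heat shock genes 10 fell and 7 were not called, also when adjusted over the list alone, at a median of -0.25 (camera adjusted p = 0.00022, and adjusted p = 0.0538 with an estimated correlation). Lysosome and autophagy genes rose in 24 of 31 cases and fell in 3 (25 and 3 when adjusted over the list alone; camera adjusted p = 1.55e-08, and adjusted p = 0.0522 with an estimated correlation). SQSTM1, an autophagy receptor gene that overlaps MRNIP in libraries that do not mark strand, rose by 2.90 ± 0.030, WIPI1 by 2.59 and NEU1 by 1.56.

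All 32 genes of G1/S and DNA replication and all 32 of the G2/M list fell in HT29 under VXN, also when adjusted over the list alone, at medians of -2.25 and -2.25 (camera adjusted p = 4.93e-30 and 1.19e-33). MCM4, RRM2, CENPF and TPX2 fell by 2.62, 2.70, 2.48 and 2.20. CDKN1A rose by 3.25 ± 0.062 and GDF15 by 2.17, while the p53 target list as a whole had 11 higher and 8 lower members (11 and 8 when adjusted over the list alone; camera adjusted p = 0.509). All 25 nuclear genes of oxidative phosphorylation fell, also when adjusted over the list alone (camera adjusted p = 2.86e-11, and adjusted p = 0.0754 with an estimated correlation), with SDHA at -1.23. Of the 13 mitochondrial mRNAs 9 fell and 4 rose, also when adjusted over the list alone (camera adjusted p = 0.0301, and adjusted p = 0.215 with an estimated correlation), MT-CO2 at -1.33, MT-CO1 at -1.16 and MT-ND2 at 0.99. Mitochondrial rRNAs took 1.95% ± 0.0094 of gene counts under VXN and 0.273% ± 0.0062 under DMSO (SD, n = 2). Cytosolic ribosomal protein genes rose in 29 of 32 cases and fell in 2 (30 and 2 when adjusted over the list alone; camera adjusted p = 1.65e-07, and adjusted p = 0.166 with an estimated correlation), RPS16 at 0.58.

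EHMT2 fell by 0.67 ± 0.044 in HT29, from 104 ± 0.031 to 65.3 ± 2.8 CPM (SD, n = 2). EHMT1 was at 81.1 ± 1.3 CPM against 85.9 ± 1.4 (SD, n = 2), with an edgeR adjusted p of 0.0891. It passed the threshold with size factors of the DESeq2 type (adjusted p = 0.0119), with no count filter (0.0341), in a fit of the HT29 libraries only (0.000455) and without t-hESC BIX replicate 2 (0.0362), each time as lower. Of the 27 genes of the H3K9 methylation machinery 11 rose and 12 fell, also when adjusted over the list alone (camera adjusted p = 0.0577). UHRF1 and SUV39H1 fell by 2.52 and 2.06, CBX1 fell from 215 ± 3.2 to 85.4 ± 0.067 CPM (SD, n = 2), and KDM7A rose by 1.48. Colon stem cell genes fell in 8 of 18 cases and rose in 4, also when adjusted over the list alone (camera adjusted p = 0.00436, and adjusted p = 0.0754 with an estimated correlation), with CD24, ALDH1A1 and CD44 at -1.80, -1.84 and -1.54. Other genes that fell were MYB at -4.21 ± 0.089, the Wnt antagonist gene DKK1 at -4.54 ± 0.068, NOX1 at -4.60 ± 0.18 and the tight junction gene CLDN2 at -3.84 (log2, SE). Of 17 fibroblast and stromal genes 12 rose and 2 fell, also when adjusted over the list alone, at a median of 2.25 (1.73 with genes at a count of 0 in one group set to their bound), and the list did not pass its test (camera adjusted p = 0.182). Of 28 pluripotency genes 9 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.484). Of 164 genes abundant in t-hESC and low in HT29, 88.4% were at higher levels in the HT29 VXN than in the HT29 DMSO libraries, at a median of 0.096% of the t-hESC level under VXN and 0.0172% under DMSO. In all, edgeR called 13490 genes, 7430 higher and 6060 lower, with 2736 and 1668 at 2-fold or more. The balance of directions depended on the processing, with 6895 higher and 6795 lower in a fit of the HT29 libraries only and 5585 and 5362 with DESeq2. It was turned in the authors' deposited table, which called 8219 genes, 3947 higher and 4272 lower, of which 8173 were tested and 8168 called here in the same direction.

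**Figure D2:**
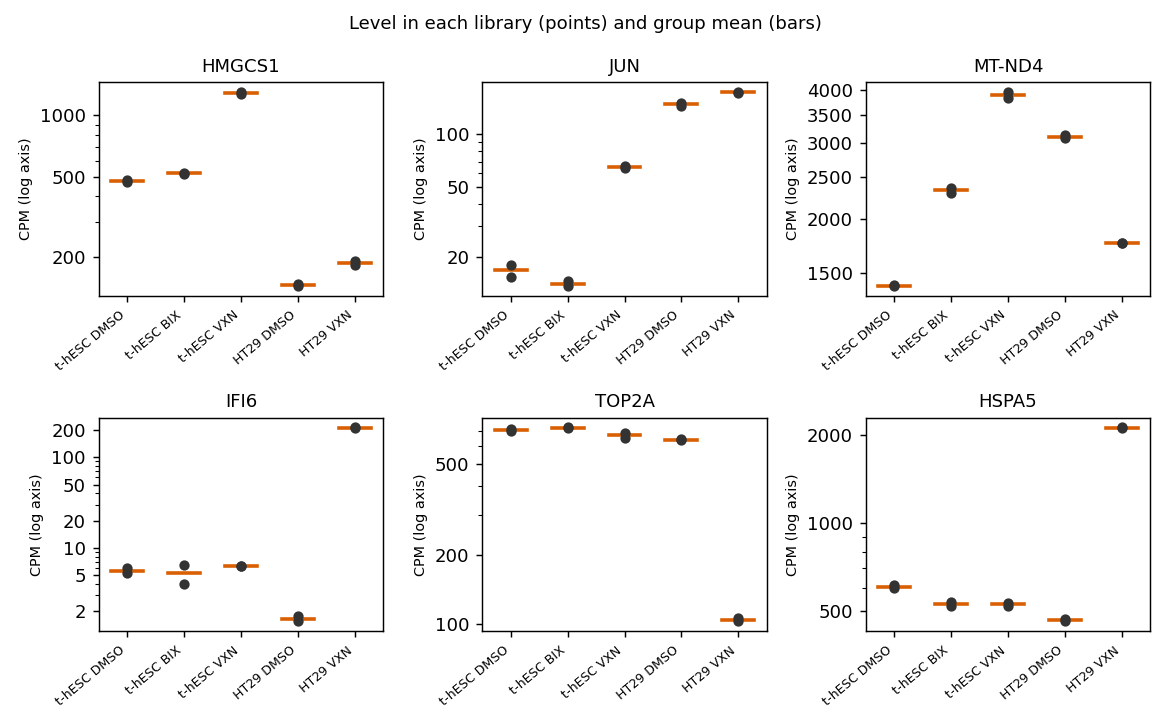
CPM (vertical log axis) of HMGCS1, JUN, MT-ND4, IFI6, TOP2A and HSPA5 in each library (points) of the 5 groups, with the group mean as a bar. IFI6 lies at 213 CPM and TOP2A at 104 CPM in HT29 VXN, against 1.65 and 641 CPM in HT29 DMSO, and HMGCS1 lies at 1290 CPM in t-hESC VXN against 473 CPM in t-hESC DMSO.

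Whether VXN acted differently in the lines was tested as an interaction, the HT29 effect minus the t-hESC effect. Cell cycle and interferon genes differed between the lines. All 32 G2/M genes and all 32 genes of G1/S and DNA replication had lower interaction values, also when adjusted over the list alone (camera adjusted p = 2.83e-54 and 7.18e-41), and all 37 interferon-stimulated genes had higher ones, also when adjusted over the list alone (camera adjusted p = 2.71e-21, and adjusted p = 0.0508 with an estimated correlation). HSPA5 rose in HT29 and fell by 0.19 in t-hESC, an interaction of 2.39 ± 0.041 (SE, edgeR adjusted p = 1.22e-51).

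Of 25 cholesterol genes 23 had lower values in HT29 than in t-hESC and 1 a higher one, also when adjusted over the list alone (camera adjusted p = 2.73e-15). In HT29 alone 14 of them rose and 9 fell (14 and 10 when adjusted over the list alone; camera adjusted p = 0.426). INSIG1 and HMGCS1 rose by 0.87 and 0.36 there, and ACAT2 fell by 1.06, where it rose by 0.70 in t-hESC. Of the 13 mitochondrial mRNAs 12 had lower interaction values and 1 was not called, also when adjusted over the list alone (camera adjusted p = 2.38e-22). MT-ND4 rose by 1.48 in t-hESC and fell by 0.82 in HT29. DUSP6 rose by 0.96 in t-hESC and fell by 0.38 in HT29, SOX9 rose by 1.31 and fell by 0.62, and TDGF1, a gene abundant in t-hESC, fell by 0.66 and rose by 1.40. JUN rose in both lines, by 1.94 in t-hESC and 0.23 in HT29. EHMT2 fell further in HT29 (interaction -0.44 ± 0.058). For EHMT1 the interaction was 0.21 ± 0.058 (edgeR adjusted p = 0.00224), a call lost with DESeq2 (adjusted p = 0.0597). In all, 9722 genes had an interaction past the threshold, 5161 higher and 4561 lower, a balance that turned to 4766 and 4945 with size factors of the DESeq2 type, 3606 and 3902 with DESeq2 and 4540 and 4567 with no count filter. The lines shared 1657 higher calls, where independent lists would share 1070 (Fisher's exact test over genes, p = 1.2e-115), and 1901 lower calls, where they would share 883. In 1170 genes the calls were opposite and the interaction was called, 641 of them higher in HT29. Across 11298 genes the log2 fold changes correlated at r = 0.328, where genes are not independent replicates.

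Finally, the lines themselves were compared. Under DMSO the pluripotency genes were higher in t-hESC, with POU5F1 at 1690 ± 21 CPM against 1.74 ± 0.4 in HT29 and SOX2 at 276 ± 8.5 against 0.148 ± 0.093 (SD, n = 2). NANOG was at 52.2 ± 1.5 CPM in t-hESC and had 2 counts over the HT29 DMSO libraries. Of 28 pluripotency genes 26 were lower and 2 higher in HT29. Of 18 genes of epithelial identity 17 were higher in HT29 and 1 lower, and all 16 goblet and secretory genes measured were higher. These counts were the same when adjusted over the list alone. The lists passed camera's test (adjusted p = 8.68e-11, 1.61e-10 and 2.82e-06) but not with an estimated correlation (adjusted p = 0.0788, 0.0846 and 0.19). EHMT1 and EHMT2 were lower in HT29 by 0.75 ± 0.040 and 0.98 ± 0.038 (SE) under DMSO. The difference under VXN was 0.54 and 1.42 in the same direction. Of 22495 genes 18996 differed under DMSO, 8741 higher and 10255 lower in HT29, and 19426 differed under VXN, 9197 higher and 10229 lower. Upper-quartile factors moved the median of all genes under DMSO by -0.11 on the log2 scale. The authors' deposited table for the lines under VXN called 17333 genes, of which 16731 were tested and 16685 called here in the same direction.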

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

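The difference of the VXN effect between the lines was planned, while the tests of repeat families were chosen only after the data were seen.

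The VXN effect differed between HT29 and t-hESC in 9722 genes. In the lists whose interaction passed camera's test, the median (HT29 minus t-hESC, log2) was 3.71 for interferon-stimulated genes, 1.76 for NRF2 targets, 1.27 for antigen presentation, 0.90 for NF-kappaB genes, 0.87 for ATF4 targets, 0.68 for the unfolded protein response, 0.67 for lysosome and autophagy, 0.53 for hypoxia and 0.42 for ribosomal proteins. It was -2.21 for G2/M, -1.84 for G1/S and DNA replication, -1.55 for mitochondrial mRNAs, -0.60 for cholesterol genes, -0.32 for immediate early genes, -0.31 for oxidative phosphorylation, -0.23 for colon stem cell genes and -0.14 for heat shock genes. With an estimated correlation the adjusted p was above the threshold for interferon-stimulated (0.0508), ribosomal protein (0.0508), oxidative phosphorylation (0.0979), colon stem cell (0.119), NF-kappaB (0.134), heat shock (0.189) and immediate early genes (0.21). With a stricter filter the camera adjusted p was 0.0822 for heat shock and 0.0909 for NF-kappaB genes.

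Single genes whose VXN effect differed between the lines had interaction values (log2) of 2.45 for SQSTM1, 2.39 for HSPA5, 2.17 for FTH1 and 2.06 for TDGF1. The values were -2.55 for TOP2A, -2.30 for MT-ND4, -2.14 for MT-CO1, -1.93 for SOX9, -1.76 for ACAT2, -1.71 for JUN, -1.34 for DUSP6, -1.18 for FDFT1 and -1.08 for HMGCS1. For EHMT1 and EHMT2 they were 0.21 and -0.44. TOP2A was not called in t-hESC (-0.073, edgeR adjusted p = 0.0538), and it was called as lower there with upper-quartile factors (edgeR adjusted p = 0.00879) and without t-hESC BIX replicate 1 (0.0324) or 2 (0.0214) or t-hESC VXN replicate 1 (0.00864). Without t-hESC VXN replicate 2 it was at -0.0399 (adjusted p = 0.435).

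Repeat families are a part of the count table that the comparisons of genes do not use. Of 1016 tested, edgeR called 326 under BIX in t-hESC (320 higher), 311 under VXN in t-hESC (300 higher) and 739 under VXN in HT29 (696 higher). Scaled by the library sizes of genes, the families moved up together, at medians over all families of 0.243, 0.226 and 0.517. The calls thus hold a broad shift, whose cause was not tested, besides changes of single families. The authors' deposited tables called 24, 21 and 335 families. The endogenous retrovirus family HERVH-int rose by 1.00 under BIX, from 1900 ± 13 to 3810 ± 68 CPM (SD, n = 2), and by 0.43 under VXN in t-hESC. In HT29 under VXN HERVH-int fell by 0.30, from 155 ± 1.8 to 127 ± 2.9 CPM (SD, n = 2), and the interaction was -0.72 (edgeR adjusted p = 1.29e-10). In t-hESC under VXN HERVK-int rose by 1.59, from 63.8 ± 0.64 to 192 ± 7.5 CPM (SD, n = 2), and LTR5_Hs by 1.26. HERVK-int also rose under BIX, by 0.87, to 117 ± 9.3 CPM (SD, n = 2). Copies of a family are near-identical, so which copies gave these reads is uncertain.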

How the results depend on the processing

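Upper-quartile factors for lists and the count without rises that carry-over would cover were the only settings chosen after the data were seen. All 7 counts of genes stayed within 1.5 times under both other scalings, both filters, the fit of only the groups compared and the replicate block. DESeq2 called 3158 genes under BIX, 4086 under VXN in t-hESC and 2982 between VXN and BIX. Of these, 3153, 4084 and 2976 were called by edgeR in the same direction. The other 4 counts of DESeq2 stayed within that range. It gave no adjusted p for 6542, 5670 and 6106 genes where its counts were lower. That number was 2181 for the interaction and 0 for VXN in HT29 and between the lines. Whether this caused the lower counts was not tested. By construction, requiring a 2-fold change left 232, 464, 4404, 389, 3260, 11779 and 12909 genes (BIX, VXN in t-hESC, VXN in HT29, VXN against BIX, interaction, lines under DMSO, lines under VXN), and shared calls of 51 for BIX and VXN and 112 for VXN in both lines. With an estimated correlation camera called 7, 9, 8, 10, 10, 0 and 1 lists in the same order of comparisons, against 15, 22, 20, 17, 17, 20 and 26. No list of the 20 called between the lines under DMSO passed with it, though 18996 genes differed there. With the replicate number as a block camera called 12 of those 45 lists in place of 20. No pairing by replicate number was seen, as deviations from group means correlated at -0.032 to 0.026 between groups over 10 pairs. Those deviations hold much counting error, so a small shared effect could go unseen. With the block 4932, 6284, 13356, 4768, 9543, 18185 and 18793 genes were called. Leaving out 1 library in turn, where the lone library is assumed to vary like the other groups, gave 3872 to 5404 genes under BIX, 4856 to 6734 under VXN in t-hESC and 12200 to 13786 under VXN in HT29. Without rises that carry-over would cover, 13445 genes were called in HT29. POU5F1 under BIX, which was not called, turned to -0.011 with no filter and ran from -0.037 to 0.037 with a library left out, and EHMT2 under BIX, not called either, ran from -0.028 to 0.087. The cause was not tested. Depth limits genes near the floor of 0.122 to 0.228 CPM.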

Other observations

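The tests of the gene length trend, the mitochondrial RNAs, the shares of t-hESC levels and the LTR families were chosen only after the results were seen, while the tests of gene lists, the carry-over markers among them, were planned.

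Genes of differentiation went both ways under VXN in HT29, and hypoxia genes rose more often than they fell. Of 16 goblet and secretory genes 6 rose and 8 fell (6 and 8 when adjusted over the list alone; camera adjusted p = 0.435). MUC5AC, a gel-forming mucin gene, rose by 2.13 ± 0.039 on the log2 scale (SE), and REG4 fell from 104 ± 3.7 to 9.72 ± 0.05 CPM (SD, n = 2). Of 16 enterocyte genes 6 rose and 5 fell (6 and 5 when adjusted over the list alone; camera adjusted p = 0.88). The keratin gene KRT20 rose from 250 ± 3.7 to 704 ± 4.9 CPM (SD, n = 2) and the brush border gene CDHR5 by 2.59, and VIL1, the villin gene, fell by 0.94. Of 23 hypoxia genes 11 rose and 3 fell (11 and 3 when adjusted over the list alone; camera adjusted p = 0.0193, and adjusted p = 0.101 with an estimated correlation). VEGFA and NDRG1 rose by 2.68 and 2.95, and CA9 fell by 3.14. The ion transporter gene SLC12A2 fell from 862 ± 4.2 to 92.5 ± 1.2 CPM (SD, n = 2).

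Long genes were higher than short genes under BIX in t-hESC (rho 0.301). The DMSO libraries alone cannot carry this trend, since rho was -0.342 between VXN and BIX. A trend of single libraries, from RNA quality or preparation, stays open: the steepest slope between replicates was 0.276 of that between BIX and DMSO. With the trend removed the medians of ribosomal protein, ribosome biogenesis and MYC, and G1/S genes were -0.122, -0.285 and -0.235, against -0.191, -0.315 and -0.270 before. The trend on length along the genome is thus not the whole cause of those falls. A trend on the length of the mRNA was not tested, and neither lists that rose nor single genes were examined with the trend removed. A direct effect of BIX on long genes was not tested.

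Mitochondrial mRNAs rose in t-hESC under both compounds. More mitochondrial RNA of every kind would raise the rRNAs as well, and under VXN the higher of both rRNA values was 0.23 against an mRNA median of 1.19. In HT29 under VXN, however, the rRNAs rose by 3.56 and 2.82 at an mRNA median of -0.39. The rRNAs thus need not track the mRNAs, and how well these libraries capture them was not tested, so they do not decide the question. For VXN, low mRNA levels in the DMSO libraries as the whole cause are excluded by the median of 0.653 between VXN and BIX. For BIX that cause was not tested and stays open. Under BIX the rRNAs were at 0.317 and -0.0213 ± 0.1 (SE) against an mRNA median of 0.421. Recovery of more mitochondrial RNA cannot be told apart there either, because the rRNAs themselves differ. For VXN an effect on mitochondrial transcripts themselves is a hypothesis, and other technical causes were not tested.

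Transcripts abundant in t-hESC were seen at low level in HT29 VXN, and carry-over of RNA or reads at a common share may be the source. Of 164 such genes 88.4% were higher in HT29 VXN than in HT29 DMSO, with a median share of 0.096% of the t-hESC level (0.0665 and 0.131% in the 2 libraries) and a slope of 0.949 on log scales. The genes were limited to a mean over both HT29 groups of at most 0.2% of the t-hESC level. This limit bounds the shares, and as it scales with the t-hESC level it could itself favour such a slope. The 17 planned carry-over markers had 5 higher and 2 lower calls, with a median of 0.66 (0.126 with genes at a count of 0 set to their bound, camera adjusted p = 0.771). At the median share 6 of them would lie under a floor of 0.152 CPM and 5 at or under their HT29 DMSO level, so the list as a whole does not decide. The other 6 all had higher means in HT29 VXN than in HT29 DMSO, the direction that carry-over would give, but not all by a clear margin. LIN28A was at 0.606 CPM against 0.0206. ESRG hardly moved, at 0.0219 CPM against 0.0206, both under the floor, where the median share would give 0.157 CPM. SOX2 had 10 counts in HT29 VXN and 7 in HT29 DMSO. The direction of these markers alone thus does not decide either. For 11 stromal genes 2-fold or more higher under VXN the median share was 1.11%, and 6 of them stood above 5 times the 90th percentile of 0.215%, among them COL6A3 at 122% and COL1A1 at 12.8%, both named after their values were seen. Whether carry-over covers the stromal genes as a set cannot be told apart, because their shares spread widely.

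A hypothesis tied to the interferon-stimulated genes was that LTR families rise more than other repeat families under VXN in HT29. The median of 533 LTR families was 0.551 and that of 483 others 0.491, a difference of 0.0605 (2-sided permutation test over families, p = 0.022). The SINE median was higher, at 0.583, and families are not independent replicates, so the difference is small and does not set LTR families apart from every class.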
